A study of Homo sapiens with 12 samples.

How the data were processed

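The series holds 12 samples of HEK293 cells, an established human embryonic kidney line that per the labels carried a transfected reporter construct. RNA was sequenced in 8 libraries: 2 treated with 5Aza-dC, 2 untreated controls, 2 labelled B21 control and 2 labelled B21 TET triple knockout. The labels do not say what B21 stands for. The other 4 samples, p65 chromatin immunoprecipitation and input DNA at 0 and 12 h of TNF, have 1 sample per condition and were not analysed here. Groups and replicate numbers were taken from the labels. The series' design text calls the 5Aza-dC and untreated replicates biological; nothing says so for the B21 libraries, so p-values there measure only the spread between these samples, which may be technical.

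Per the labels' protocols, total RNA was extracted by column, cDNA was primed with oligo-dT, and the RNA libraries were made by BGI for the BGISEQ-500 sequencer. Per the submitters' processing notes, STAR, Cuffdiff and the genome build hg38 belong to these libraries, and the notes of the 5Aza-dC experiment also name Bowtie2 2.3.4.2 and SAMtools, with no role given for any tool. The deposited values are FPKM, fragments per kilobase of transcript scaled to library size, per the file headers, with 1 value per versioned Ensembl gene. The files of the 5Aza-dC experiment are named as RPKM tables while their column header reads FPKM; whether the fragments were single or paired was not given in the sources used here. Whether the libraries kept strand was not given either, so genes that overlap on the same or opposite strand cannot be told apart by their values. An oligo-dT primed library favours the 3′ part of polyadenylated transcripts, and a gene-level FPKM sums over transcripts, so it reports neither a small deletion within an exon nor transcripts without a poly(A) tail.

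The files hold no read counts. The commonest ratio between libraries of the values of genes under 0.3 FPKM, shared by 511 to 1327 genes per pair, was read as the ratio of what 1 fragment is worth and so of depth. The 5Aza-dC libraries had relative depths of 1 and 0.988 and their controls 0.992 and 0.973. The B21 control libraries had relative depths of 1 and 1.10, and the libraries labelled knockout 1.16 and 1.41. Absolute depth is unknown and the gene lengths used were not given in the sources used here, so whole reads were not recovered and no counting interval or count test was made. The estimator was tested on simulated counts of 20000 genes and returned relative depths of 1.0, 1.1 and 1.4 where these had been set.

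The files listed 60687 to 60707 genes each. Genes missing from some files were left out and not set to 0: 60674 genes stood in all 4 files of the 5Aza-dC experiment, 60704 in all 4 of the B21 experiment and 60662 in all 8. Gene names are those in the files, and 93.1% of the gene identifiers matched the gene name table used here. A gene listed at 0 can be a failed estimate as well as an absent transcript, so no fold is given against a group at 0. Levels were not compared across the experiments. The files hold no coordinates. Chromosomes and gene coordinates were taken by gene symbol from a separate RefSeq gene table, and the text gives no exon or untranslated region.

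Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 2-sided), separately within each experiment, over genes at 1 FPKM or more in at least 2 of the 4 libraries. All fold changes are on that log2(FPKM + 1) scale, which understates the change of genes near 1 FPKM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the words rose and fell are used of called genes. Each group had 2 libraries, which leaves 2 residual degrees of freedom; limma's prior added 4.38 in the 5Aza-dC experiment and 4.09 in the B21 experiment. The difference between the effects was a limma contrast over all 8 libraries, each effect against its own control, over genes at 1 FPKM or more in at least 2 of the 8. The overlap of calls was tested with Fisher's exact test, 2-sided, per pair of directions, over genes tested in both experiments; genes are not independent replicates.

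The lists, all fixed before the data were examined, were TET enzymes, DNA methylation machinery, germline and cancer-testis genes, imprinted genes, interferon-stimulated genes, NF-kB target genes, TNF receptor signalling components, p53 target genes, DNA replication genes, mitosis genes, replication-dependent histone genes, metallothionein genes, the protocadherin beta cluster, chromosome 19q13 zinc finger genes, HOX genes, cholesterol synthesis and uptake genes, integrated and unfolded protein stress genes, hypoxia and glycolysis genes, immediate-early and heat shock genes, MHC class I presentation genes, pluripotency genes, housekeeping genes, cytosolic ribosomal protein genes, mitochondrially encoded genes, and markers of epithelial, mesenchymal, neuronal, blood and kidney cells. Those with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry stood beside it. Camera compares a list with the other genes, while fry asks whether its members move, on balance, one way.

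The genes named in the text follow a rule that was also fixed before the data were examined. It takes TET1, TET2, TET3, DNMT1, DNMT3A, DNMT3B, UHRF1 and IL32 whatever their result, then per comparison the 10 genes with the largest called change in each direction whose libraries of one group all lay above those of the other, leaving out names that are not gene symbols or stand for several genes, up to 4 members per list with the smallest p, and up to 5 genes per pair of directions for the overlap and per direction for the difference. Other genes named were chosen after their values were seen, and the text says so. Some genes that this rule takes are not reported.

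The alternatives, also fixed beforehand, were a pseudocount of 0.1, no minimum, a minimum of 5 FPKM, 2 scalings between libraries (equal medians, quantile normalization), the replicate number as a block, all 8 libraries in one fit, a robust prior, a call that also asks for a 2-fold change, camera with an estimated correlation, fry, and leaving out each library in turn. After the chromosome pattern was seen, subtracting the local chromosome median was added: the median log2 fold change of the 100 nearest tested genes on the chromosome was taken off a gene's effect before the fit. A crossed pairing of the B21 replicates was added likewise. A test of whether 1 B21 control library stood apart was also run and dropped, because the calls themselves fix its outcome. A value counts as reversed where its sign changed and it was called in either fit; this rule was narrowed after a first version, which counted every change of sign, had been run.

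Limma, the contrast, camera with the preset correlation and the local median were tested on simulated data built from the real levels and spread, with known changes. Fry, camera with an estimated correlation, Fisher's exact test and the shuffles and random lists given at the end were not. In the 5Aza-dC design limma recovered 90.5% of genes changed 1.5-fold and 100% of those changed 2-fold, with 25 false calls among 15304 genes. These 25 stood beside 57, 64 and 73 true calls at 1.5-fold, 2-fold and 4-fold. In the B21 design it recovered 50.8% at 1.5-fold and 98.5% at 2-fold, with 16 false calls among 13108 genes. These 16 stood beside 33, 66 and 68 true calls. In both designs false calls were thus a larger share of all calls than the adjusted p threshold of 0.05 is meant to allow. The contrast of effects recovered 26.8% at 1.5-fold and 85.9% at 2-fold, with 5 false calls among 12960 genes. These 5 stood beside 19, 55 and 65 true calls, a share under that threshold. Camera found the raised list in both designs, with no false call. The simulated noise was independent between genes, while the estimated correlation of the real lists reached 0.804 (mitochondrially encoded genes with 5Aza-dC). The simulation therefore does not test false calls of lists whose members vary together. Both groups of a design were given the same spread, which was not so for the B21 pairs. The local median recovered a simulated shift of a whole chromosome at a ratio of 0.992 in the 5Aza-dC design and 1.023 in the B21 design. A shift of part of a chromosome was not simulated. Joining, depth and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.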

Results

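The study asked how tumour necrosis factor (TNF) induces IL32, which encodes a proinflammatory cytokine, in HEK293 cells. The RNA libraries bear on DNA methylation. 5Aza-dC (5-aza-2′-deoxycytidine) is a cytosine analogue that is built into DNA and traps DNA methyltransferases, so that methylation falls as cells divide. TET1, TET2 and TET3 encode enzymes that oxidise 5-methylcytosine, a step towards its removal. Untreated cells were the controls of the 5Aza-dC libraries. B21 control cells were those of the libraries labelled TET triple knockout. Each of the 4 groups had 2 libraries. Genes at 1 FPKM or more numbered 15177 and 15197 in the treated libraries, 15523 and 15488 in their controls, 12948 and 12820 in the B21 controls and 13292 and 13312 in the libraries labelled knockout. Across genes, the SD of the log2 difference between replicates was 0.201 for the treated pair, 0.196 for the untreated pair, 0.338 for the B21 control pair and 0.149 for the pair labelled knockout.

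The first comparison asked which genes change when methyltransferases are inhibited. IL32 (ENSG00000008517.16, chromosome 16, 3065403 to 3069530) stood at 15.3 and 15 FPKM in the treated libraries and at 1.15 and 0.879 in the untreated ones, 14.9-fold higher by the means (log2 fold change 3.01, SE 0.118, limma adjusted p = 0.000207). The neutrophil-attracting chemokines CXCL1 and CXCL8 and the chemokine CCL20 rose more. CXCL1 went to 24.5 and 25.9 FPKM from 0.652 and 0.828, CXCL8 to 13.6 and 13.8 from 0.39 and 0.633, and CCL20 to 19.6 and 15.7 from 0.308 and 0.393. GTSF1, a germ cell factor of small RNA silencing, rose with them, as did CGA, the alpha subunit of the glycoprotein hormones. DDIT4, an inhibitor of the growth kinase mTOR that low oxygen and nutrient stress induce, fell and was at 19.3 and 17.6 FPKM against 100 and 98.6.

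The other leading genes that rose were PNMA5, at 12.6 and 10.8 FPKM against 0.0841 and 0.0172, GAGE2A, ACRC (log2 fold change 3.25), PEG10 (2.94), CGA (2.65) and GTSF1, at 6.03 and 4.48 FPKM against 0.0911 and 0.103. ACRC, now named GCNA, encodes a germ cell nuclear protease, and PEG10 is a retrotransposon-derived gene expressed from the paternal copy. GAGE2A, a cancer-testis antigen gene, was listed at 0 in both untreated libraries and at 6.5 and 12 FPKM in the treated ones. It is one of several near-identical copies, so its value is uncertain. Below DDIT4 (−2.37), the leading genes that fell were ANKRD37 (−2.29) and HILPDA (−2.01), both induced by hypoxia, NOG (−2.28), a secreted BMP antagonist, STC1 (−2.08), a secreted glycoprotein, and NRN1 (−2.02), a neurite growth factor. Next came SDHAF4 (−1.92), an assembly factor of succinate dehydrogenase, LOX (−1.86), which crosslinks collagen, LINC00173 (−1.83) and BLOC1S5-TXNDC5 (−1.69). BLOC1S5-TXNDC5 is a read-through transcript that shares exons with its neighbours. Its untreated libraries stood at 1.2 and 4.23 FPKM, and its value is uncertain. The 20 leading genes, IL32 and the chemokines among them, had adjusted p-values of 0.00017 to 0.0171, with a SE of 0.065 to 0.382.

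Of 15764 genes tested, 3105 rose and 2894 fell, 38.1% of them; at a change of at least 2-fold, 232 rose and 243 fell. In 72.1% of the tested genes the groups did not overlap, where chance gives 33.3% for 2 against 2. With no minimum level, which tests 36759 genes, 1061 rose and 644 fell, and without untreated control 1 or control 2 the changed genes numbered 3608 and 3857. Among the genes named for this comparison, ANXA3, BLOC1S5-TXNDC5, CDC6, CDH1, CECR7, CPS1, GSTA4, HIST1H1C, HMGCS1, RELA, RPL7A and ZNF480 lost their call with no minimum (adjusted p = 0.0503 to 0.144).

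**Figure D1:**
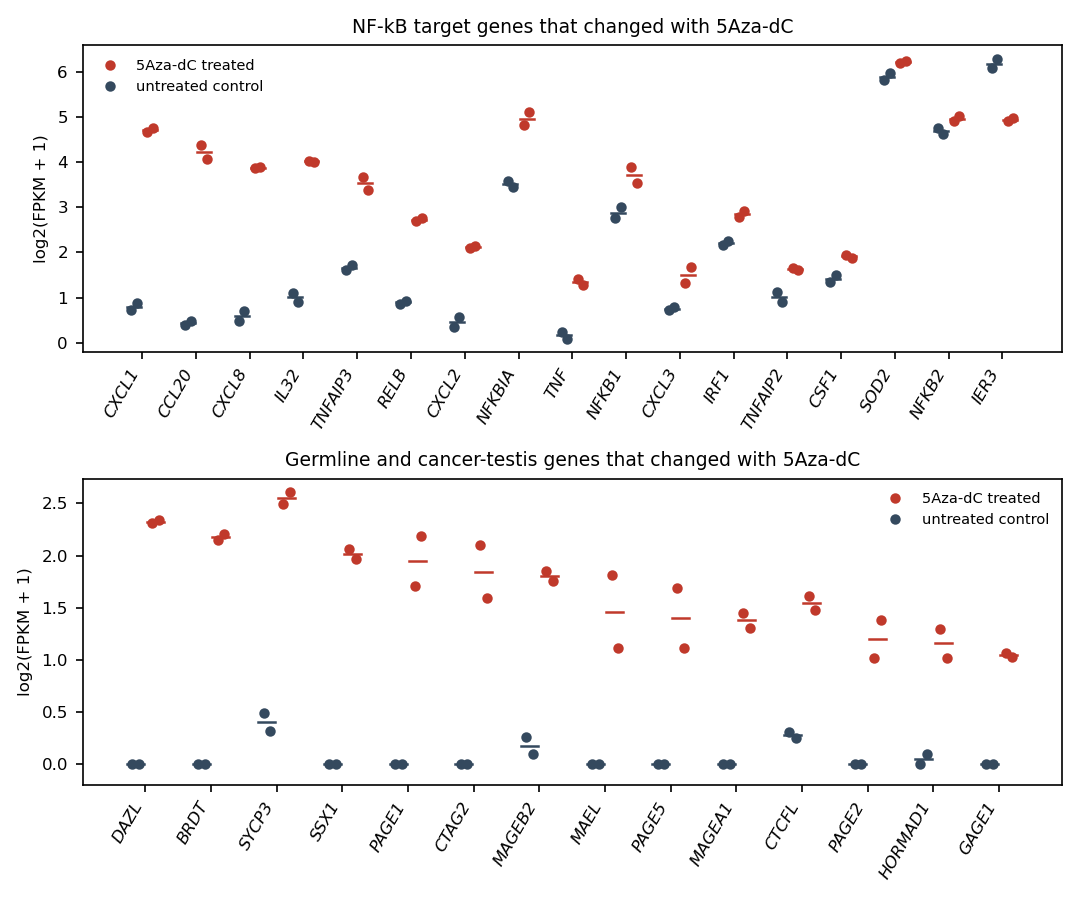
Each point is 1 library's log2(FPKM + 1), with a bar at the mean of the 2 libraries of a group, for the NF-kB target genes (top) and the germline and cancer-testis genes (bottom) that changed with 5Aza-dC. In the top panel 16 genes lie higher in the treated libraries and IER3 lies lower; in the bottom panel all 14 genes lie higher.

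Of the genes that write, keep and erase DNA methylation, TET3 rose to 11.2 and 10.9 FPKM from 5.66 and 5.85 (log2 fold change 0.84, SE 0.092, adjusted p = 0.00234). UHRF1, which brings DNMT1 to newly copied DNA, rose by 0.69 (adjusted p = 0.00267) and DNMT3B, a de novo methyltransferase, by 0.46 (adjusted p = 0.0083). DNMT1, the maintenance methyltransferase, rose by 0.35 (SE 0.104, adjusted p = 0.0415). That call was lost with quantile normalization (0.11), with no minimum (0.184), with the local chromosome median subtracted (0.0559) and with all 8 libraries in one fit (0.0537). It was also lost without treated library 2 (0.145) or untreated control 1 (0.167). TET1 (−0.31, adjusted p = 0.0606; 0.0495 with a minimum of 5 FPKM), TET2 (−0.12, adjusted p = 0.437) and DNMT3A (−0.09, adjusted p = 0.428) did not pass. The DNA methylation machinery list rose as a whole (camera adjusted p = 0.0329; adjusted p = 0.49 with an estimated correlation). Of its 16 tested members 7 rose, 1 fell and 8 did not pass, and 7 rose and 1 fell adjusted over the list alone. GADD45B, a stress-response gene, rose most among its named members (1.24), and MBD1, which binds methylated DNA, rose by 0.48. The call of that list was lost with quantile normalization (adjusted p = 0.178), a minimum of 5 FPKM (0.109) and without untreated control 1 (0.0754).

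The NF-kB target list, genes that the p65 family of transcription factors switches on, rose (camera adjusted p = 6.24e-06; adjusted p = 0.403 with an estimated correlation). Of 23 tested members 16 rose, 1 fell and 6 did not pass, and 18 rose and 2 fell adjusted over the list alone. Of the 16, 7 were under 1 FPKM in both untreated libraries. With no minimum 9 of 29 rose and 1 fell (camera adjusted p = 2.81e-06). Besides the chemokines and IL32, RELB, which encodes an NF-kB subunit, stood at 5.47 and 5.72 FPKM against 0.822 and 0.89. The member that fell was IER3, an early response gene (−1.23, adjusted p = 0.00121). TNFAIP3 and NFKBIA, which encode inhibitors of the pathway, rose by 1.86 and 1.46, and TNF itself rose to 1.64 and 1.41 FPKM from 0.187 and 0.0638 (adjusted p = 0.00416). RELB, IER3 and these 3 members were picked after their values were seen. The TNF receptor signalling list was not called (camera adjusted p = 0.568), with 3 of 15 members higher over all genes and 3 adjusted over the list alone. They were RELA, which encodes p65 (0.57, adjusted p = 0.00597), RIPK1 (0.35) and TRAF2 (0.34). The call of TRAF2 was lost with the local chromosome median subtracted (adjusted p = 0.0973), with no minimum (0.0688), with all 8 libraries in one fit (0.0689) and without treated library 1 (0.0852), untreated control 1 (0.083) or control 2 (0.0566). That of RIPK1 was lost with no minimum (0.0806) and without treated library 1 (0.0764) or untreated control 1 (0.0938).

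Germline and cancer-testis genes gave the lowest camera p of the 24 lists (adjusted p = 1.69e-08; adjusted p = 0.403 with an estimated correlation). Of its 46 genes 16 reached the tested level. Of these 14 rose, none fell and 2 did not pass, and 15 rose adjusted over the list alone. All 14 were under 1 FPKM in both untreated libraries, so they reached that level only through the treated ones. With no minimum 41 of the genes were tested, 40 had a log2 fold change above 0, 17 rose and none fell (median 0.59, camera adjusted p = 1.35e-15). DAZL, an RNA-binding regulator of germ cells, was listed at 0 in both untreated libraries and at 3.95 and 4.08 FPKM in the treated ones. BRDT, a testis bromodomain gene, was likewise listed at 0 and at 3.44 and 3.63, and SSX1, which has close paralogs, at 0 and at 3.16 and 2.92. SYCP3, part of the meiotic chromosome axis, stood at 4.64 and 5.09 FPKM against 0.402 and 0.248. At a minimum of 5 FPKM, or without 1 treated library, the list had too few members for the test. Imprinted genes, expressed from 1 parental copy, moved both ways: 6 of 13 rose and 3 fell, the same counts adjusted over the list alone. The list was not called by camera (adjusted p = 0.174, and 0.0102 with no minimum) and was called higher by fry (adjusted p = 0.0217). PEG10, PHLDA2 (1.15), MEST (1.66) and NNAT (1.43) were the members with the smallest p, and all rose.

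Hypoxia and glycolysis genes fell (camera adjusted p = 1.2e-06; adjusted p = 0.49 with an estimated correlation). Of 18 tested members 11 fell, none rose and 7 did not pass, and 12 fell adjusted over the list alone. Besides ANKRD37, NDRG1 was at 104 and 116 FPKM against 260 and 322, and PDK1 (−1.02), which diverts pyruvate from the mitochondria, and ALDOC (−1.04), a glycolytic aldolase, fell. Integrated and unfolded protein stress genes fell as a list (camera adjusted p = 0.00473; adjusted p = 0.49 with an estimated correlation), with 10 of 21 lower, 3 higher and 8 not passing, and 13 lower and 3 higher adjusted over the list alone. ASNS, asparagine synthetase, was at 72.3 and 64.6 FPKM against 187 and 186, and VLDLR, a lipoprotein receptor, fell by 0.87, while HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.56. Cholesterol synthesis and uptake genes were lower as a list by camera (adjusted p = 0.00891; adjusted p = 0.696 with an estimated correlation) and not called by fry (adjusted p = 0.0568): 12 of 19 fell, 1 rose and 6 did not pass, while 12 fell and 3 rose adjusted over the list alone. INSIG1, a sterol-sensing regulator, was at 36 and 34.5 FPKM against 103 and 108. The enzymes MSMO1 (−1.08) and HMGCS1 (−0.92) fell. Cytosolic ribosomal protein genes were lower as a list by camera (adjusted p = 0.00136; adjusted p = 0.696 with an estimated correlation) and not called by fry (adjusted p = 0.109). Of 26 members 8 fell, none rose and 18 did not pass, and 6 fell adjusted over the list alone. RPL3 (−0.66) and RPL7A (−0.45) fell most clearly.

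Lists of DNA replication, mitosis, p53 target, immediate-early and 19q13 zinc finger genes were higher, with part of their members called. DNA replication genes (camera adjusted p = 0.00552; adjusted p = 0.49 with an estimated correlation) had 10 of 25 members higher and 1 lower, or 11 and 1 adjusted over the list alone. Among them were RRM2, a subunit of ribonucleotide reductase (0.72), FEN1, a flap endonuclease (0.70), CCNE1 (0.58) and CDC6 (0.67). Mitosis genes (camera adjusted p = 0.00903; adjusted p = 0.49 with an estimated correlation; fry adjusted p = 0.0568, not called) had 6 of 20 higher and 1 lower, or 9 and 1 adjusted over the list alone. CDC20, an activator of the anaphase ligase, rose by 0.72 and BIRC5, survivin, by 0.51. Both calls were lost with quantile normalization (adjusted p = 0.178 and 0.46), and that of the mitosis genes also with a minimum of 5 FPKM (0.0552) and without untreated control 1 (0.0542). p53 target genes (camera adjusted p = 0.0119; adjusted p = 0.49 with an estimated correlation) had 13 of 27 higher and 2 lower, or 13 and 4 adjusted over the list alone. AEN, a nuclease, was at 39.1 and 36.1 FPKM against 11.6 and 11.4, CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.82 and TIGAR by 0.78. Immediate-early and heat shock genes (camera adjusted p = 0.00891; adjusted p = 0.49 with an estimated correlation) had 8 of 13 higher and 1 lower, the same adjusted over the list alone. HSPH1, a chaperone, rose by 1.32, BAG3, a co-chaperone, by 0.76 and the early transcription factor EGR1 by 1.73, and JUN fell by 0.69. At a minimum of 5 FPKM the p53 (adjusted p = 0.0757) and immediate-early (0.0926) calls were lost. Chromosome 19q13 zinc finger genes (camera adjusted p = 0.0468; adjusted p = 0.49 with an estimated correlation) had 5 of 23 higher and 1 lower, the same adjusted over the list alone, with ZNF480 higher by 0.77 and ZNF83 lower (−0.40). That call was lost with the local chromosome median subtracted (adjusted p = 0.222), a minimum of 5 FPKM (0.425), and without treated library 1 (0.095), control 1 (0.135) or control 2 (0.0844). That of ZNF83 was lost with no minimum (0.128) and without the same 3 libraries (0.0839, 0.0635 and 0.0753).

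The remaining lists were not called by camera in the 5Aza-dC comparison. Interferon-stimulated genes (camera adjusted p = 0.826) had 2 of 23 higher and 3 lower, or 1 and 2 adjusted over the list alone; IFIT1 fell by 1.18. MHC class I presentation genes (adjusted p = 0.47) had 5 of 13 higher and 1 lower, the same adjusted over the list alone, with B2M, the light chain of MHC class I, higher by 0.34, a call that was lost with no minimum (adjusted p = 0.0558) and without untreated control 1 (0.0541). HOX genes (adjusted p = 0.849) had 2 of 35 higher and 5 lower, the same adjusted over the list alone, HOXD13 higher by 0.39 and HOXD8 lower (−0.52), though not with no minimum (adjusted p = 0.084) or without untreated control 1 (0.055). Histone genes (adjusted p = 0.867) had 2 of 7 lower, the same adjusted over the list alone, HIST1H1C by −0.65. Housekeeping genes (adjusted p = 0.826) had 2 of 14 higher and 2 lower, the same adjusted over the list alone. POLR2A rose by 0.78 and ACTB by 0.48, and GAPDH (−0.42) fell. The call of GAPDH was lost with quantile normalization (adjusted p = 0.213), with no minimum (0.134) and without untreated control 1 (0.0583) or control 2 (0.136), and that of ACTB with no minimum (0.103) and without control 1 (0.0912). Mitochondrially encoded genes (adjusted p = 0.38) had 1 of 13 higher, MT-ND1 (0.62, adjusted p = 0.031), and none adjusted over the list alone; the list was called without treated library 1 (adjusted p = 0.00354). The MT-ND1 call was lost with no minimum (adjusted p = 0.195) and without treated library 2 (0.0652), untreated control 1 (0.145) or control 2 (0.0529). Metallothionein (3 tested), TET enzyme (3), pluripotency (3) and kidney marker (4) genes were too few for the test, and no protocadherin beta gene reached the tested level. Among these, LIN28B, an RNA-binding pluripotency factor, rose by 0.56, LRP2, the endocytic receptor megalin, fell by 1.06 and GATA3 rose by 0.51. The GATA3 call was lost with no minimum (adjusted p = 0.145) and without treated library 1 (0.0685), treated library 2 (0.0769) or untreated control 1 (0.0901). No metallothionein gene passed. Adjusted over the list alone the counts were 1 and 1 for TET enzymes, none for metallothioneins, 1 and 0 for pluripotency genes and 1 and 1 for kidney markers, higher and lower.

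Markers of other cell types went both ways with 5Aza-dC. Epithelial markers (camera adjusted p = 0.826) had 6 of 13 higher and 2 lower, or 6 and 4 adjusted over the list alone. KRT18 rose by 0.67 and KRT19, listed at 0 in both untreated libraries, was at 1.95 and 1.46 FPKM, while CDH1, E-cadherin, fell by 0.85. Mesenchymal markers (camera adjusted p = 0.589) had 5 of 17 higher and 4 lower, or 5 and 5 adjusted over the list alone. SPARC, a matrix glycoprotein, was higher by 1.68, VIM, vimentin, by 0.62 and LOX was lower. Fry called the mesenchymal list higher (adjusted p = 0.0304). Neuronal markers (camera adjusted p = 0.746) had 4 of 12 higher and 3 lower, or 5 and 5 adjusted over the list alone. TUBB3, neuronal tubulin, rose by 1.53 and ENO2, neuronal enolase, fell by 0.80. The neuronal list too was called higher by fry (adjusted p = 0.0234). Blood cell markers (adjusted p = 0.867) had 1 of 6 higher and 1 lower, the same adjusted over the list alone. CD74, the invariant chain of MHC class II, was at 5.8 and 5.88 FPKM against 0.351 and 0.66, and LCP1 fell by 0.29. The LCP1 call was lost with no minimum (adjusted p = 0.0635) and without treated library 1 (0.0669), treated library 2 (0.0548) or untreated control 2 (0.0932). The medians of the epithelial (−0.09), blood (−0.03) and interferon (−0.003) lists were below 0 while their means and camera directions were up. Those of the histone (0.07) and HOX (0.009) lists were above 0 with means and camera directions down, and the untested TET enzyme list had a median of −0.12 and a mean of 0.14.

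The second comparison set libraries labelled TET triple knockout against B21 controls. TET1 stood at 1.07 and 1.38 FPKM in the libraries labelled knockout and at 2.99 and 3.55 in the controls (log2 fold change −0.94, SE 0.157, adjusted p = 0.0421). TET2 was at 5.74 and 5.81 FPKM against 3.5 and 4.54 (0.44, adjusted p = 0.144) and TET3 at 7.84 and 8.56 against 7.76 and 7.83 (0.06, adjusted p = 0.782). RNA levels per gene do not show whether a coding sequence was disrupted by a small insertion or deletion, so these values check the label only in part. The TET1 call was lost with no minimum level (adjusted p = 0.154), with the local chromosome median subtracted (0.0535) and without knockout library 1 (0.23). DNMT3B was at 3.89 and 4.16 FPKM against 7.39 and 5.85 (−0.59, adjusted p = 0.0855), and DNMT1 (0.11, adjusted p = 0.6), DNMT3A (0.25, 0.304) and UHRF1 (−0.12, 0.528) did not pass either. With all 8 libraries in one fit DNMT3B was called lower (limma adjusted p = 0.0127) and TET2 higher (0.0464). IL32 was at 0.921 and 0.802 FPKM against 0.22 and 0.0865, below the level tested and 5.62-fold higher by the means. With no minimum its log2 fold change was 0.69 (SE 0.106) and did not pass (limma adjusted p = 0.142). At such levels the log2(FPKM + 1) scale understates a change.

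HSPB8 and CGA rose most and CTSZ fell most in the libraries labelled knockout. HSPB8, a small heat shock protein, was at 14.5 and 15.5 FPKM against 0.298 and 0.595 (log2 fold change 3.48, SE 0.159, adjusted p = 0.0068), and CGA, which also rose with 5Aza-dC, at 8.78 and 6.9 against 0.127 and 0. The axonal motor KIF1A was at 34.1 and 35.7 FPKM against 8.75 and 6.74 and EEF1A2, the elongation factor form of neurons and muscle, at 134 and 140 against 38.2 and 29.8. CTSZ, a lysosomal protease, was at 0.0368 and 0.0475 FPKM against 9.43 and 7.04 (−3.14, SE 0.174, adjusted p = 0.00744). GSTP1, a glutathione transferase, was at 5.74 and 5.62 FPKM against 21.5 and 16.7.

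The other leading genes that rose were SHC2 (2.27), a signalling adaptor, SYTL5 (2.25), ANXA1 (2.12), a phospholipid-binding annexin, ANKRD1 (2.07), JAKMIP2 (2.00) and CRABP2 (1.96), which carries retinoic acid. Those that fell were TCEAL3 (−1.98), SOWAHC (−1.85), OXCT1 (−1.83), which breaks down ketone bodies, MARVELD2 (−1.76), tricellulin of epithelial junctions, NBL1 (−1.64), a secreted BMP antagonist, CECR7, MYOM2 (−1.59), a sarcomere protein, GSTP1 (−1.58) and LPAR6 (−1.57), a lysophosphatidic acid receptor. CECR7, a non-coding RNA, was listed at 0 in both libraries labelled knockout and at 2.2 and 1.93 FPKM in the controls. The 20 leading genes had adjusted p-values of 0.0068 to 0.0229.

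**Figure D2:**
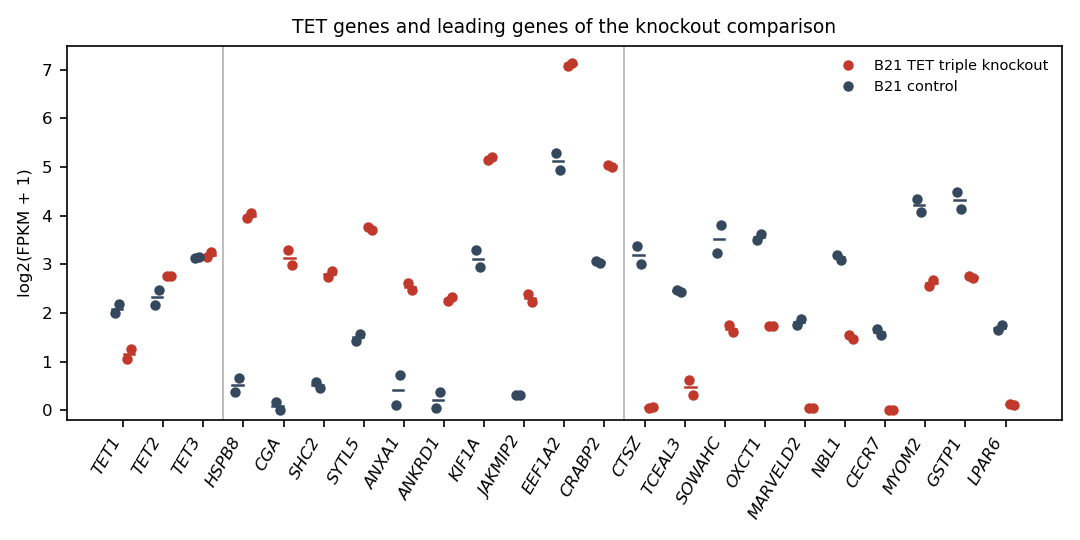
Each point is 1 library's log2(FPKM + 1), with a bar at the mean of the 2 libraries of a group, for the TET genes (left), the leading genes that rose (middle) and those that fell (right) in libraries labelled TET triple knockout. TET1 lies lower in the libraries labelled knockout at 1.07 and 1.38 FPKM, and TET2 and TET3 do not.

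Of 13364 genes tested, 266 rose and 262 fell, and at a change of at least 2-fold 112 rose and 65 fell. In 59.1% of the tested genes the groups did not overlap, where chance gives 33.3%. The calls lay unevenly along the genome. The median log2 fold change was −0.38 on chromosome 11, −0.27 on chromosome 8, −0.25 on chromosome 22 and −0.17 on chromosome 5. Of the 13364 tested genes 674, 432, 297 and 572 lay on these 4 chromosomes, in that order. The 4 together held 130 of the 262 genes that fell and 14 of the 266 that rose. The B21 control libraries themselves differed by chromosome, control 1 minus control 2 ranging from a median of −0.15 on chromosome 4 to 0.31 on chromosome 19. On chromosomes 11, 8, 22 and 5 it was 0.10, −0.08, 0.24 and −0.12. Library 1 minus 2 of the pair labelled knockout ranged the other way, from −0.07 on chromosome 19 to 0.04 on chromosome 4. With equal medians 221 genes rose and 358 fell, and with quantile normalization 169 and 253. With no minimum level limma called 0 of 27404 genes (4615 at an unadjusted p under 0.05), so that no gene named here kept its call. The number of changed genes was 227 with a minimum of 5 FPKM, 171 with the local chromosome median subtracted and 2614 with all 8 libraries in one fit. It was 5328 without control 1, 6231 without control 2, 125 without knockout library 1 and 160 without knockout library 2.

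**Figure D3:**
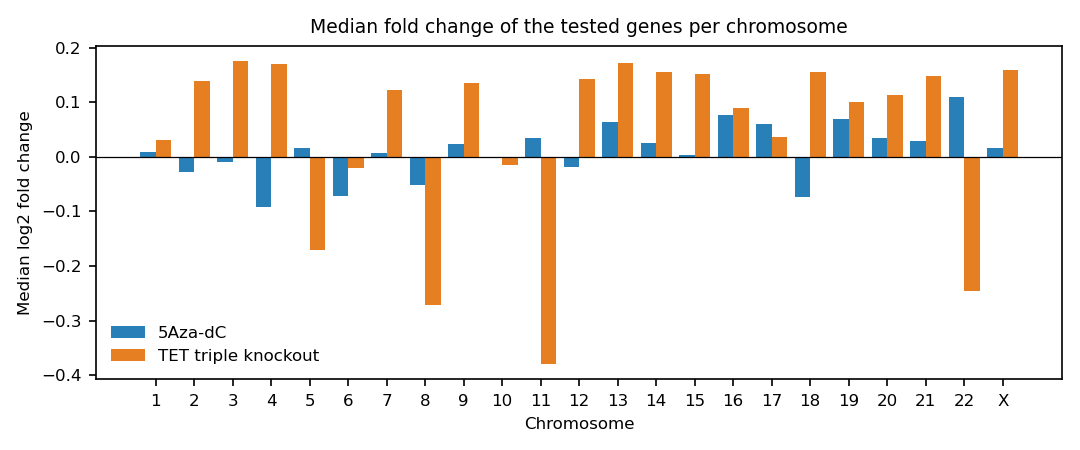
Bars give the median log2 fold change of the tested genes on each chromosome for 5Aza-dC against untreated cells and for libraries labelled TET triple knockout against B21 controls. The 5Aza-dC medians lie between −0.092 and 0.11, and those of the knockout comparison fall to −0.379 on chromosome 11.

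Developmental transcription factors of the HOX clusters were lower in the libraries labelled knockout (camera adjusted p = 5.76e-05; adjusted p = 0.57 with an estimated correlation). Of 34 tested members 3 fell, none rose and 31 did not pass, and 11 fell adjusted over the list alone. HOXA5 was at 13.8 and 15.1 FPKM against 28.1 and 25.6, HOXB6 at 8.67 and 11.2 against 25.1 and 20.8, and HOXB5 at 3.37 and 3.69 against 7.25 and 6.44. All 3 lost their call without knockout library 1 (adjusted p = 0.279, 0.0967 and 0.357), and HOXA5 (0.123) and HOXB5 (0.197) also without knockout library 2. HOXB5 was not called with the local chromosome median subtracted either (0.0545), while the list was. The mitochondrially encoded list was lower (camera adjusted p = 0.00207; adjusted p = 0.553 with an estimated correlation) with no member called over all genes and 4 lower adjusted over the list alone; MT-CYB had −0.31 and MT-CO3 −0.29. That call was lost with quantile normalization (adjusted p = 0.916), without control 2 (0.0962) and with all 8 libraries in one fit (0.06).

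Replication-dependent histone genes were higher as a list (camera adjusted p = 0.0166, and 0.553 with an estimated correlation). Of 18 genes in the list 8 were tested, with none called over all genes and 4 higher adjusted over the list alone. These oligo-dT primed libraries do not report histone transcripts without a poly(A) tail. HIST1H2AC was at 4.84 and 5.41 FPKM against 2.64 and 3. The call was lost with the local chromosome median subtracted (adjusted p = 0.0858), with no minimum (0.23) and without control 2 (0.0962). Chromosome 19q13 zinc finger genes were higher (camera adjusted p = 0.0166; adjusted p = 0.553 with an estimated correlation) with none of 22 called over all genes or adjusted over the list alone. ZNF160 had 0.56 and ZNF761 0.51. The median of all tested genes on chromosome 19 was 0.10 in this comparison, and B21 control 1 lay above control 2 there by a median of 0.31. The call was lost with quantile normalization (adjusted p = 0.0689), with no minimum (0.139), with a minimum of 5 FPKM (0.211) and without control 1 (0.265). Integrated and unfolded protein stress genes were higher (camera adjusted p = 0.0482; adjusted p = 0.553 with an estimated correlation). PPP1R15A, which helps end the stress response, was at 8.94 and 8.64 FPKM against 4.96 and 5.22 and was the 1 of 21 called, and 6 were higher adjusted over the list alone. Epithelial markers were higher (camera adjusted p = 0.0482; adjusted p = 0.553 with an estimated correlation), with 2 of 8 called and 3 adjusted over the list alone. They were KRT8, keratin 8, at 38.8 and 35.7 FPKM against 21 and 19.3 and SPINT1, a protease inhibitor, at 2.1 and 1.97 against 0.701 and 0.503. The stress call was lost with a pseudocount of 0.1 (adjusted p = 0.0529), all 8 libraries in one fit (0.06), a minimum of 5 FPKM (0.0863) and without control 2 (0.0969) or knockout library 1 (0.114). The epithelial call was lost with the same 5 (adjusted p up to 0.211), with no minimum (0.0806), quantile normalization (0.0689) and without control 1 (0.0725) or knockout library 2 (0.0834). PPP1R15A (adjusted p = 0.0813) and SPINT1 (0.0717) were not called with the local chromosome median subtracted or with quantile normalization (0.0615 and 0.0561). PPP1R15A was not called with a pseudocount of 0.1 (0.0516), a minimum of 5 FPKM (0.053) or equal medians (0.0525) either. Without knockout library 1 or 2, PPP1R15A (0.486 and 0.371) and KRT8 (0.269 and 0.119) lost their calls and SPINT1 was not tested.

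Single members moved in lists that were not called. CDKN1A, 1 of 25 p53 target genes (camera adjusted p = 0.987), was at 13.2 and 12 FPKM against 3.95 and 3.24, and GADD45A, 1 of 16 in the methylation machinery list (0.508), rose by 0.81. Each was also the only member called adjusted over the list alone. INSIG1 and HMGCS1 rose by 1.17 and 1.12 in the cholesterol list (0.372) and FDFT1, at 48.1 and 47.6 FPKM against 85.7 and 75.2, fell, or 4 higher and 1 lower of 19 adjusted over the list alone. FDFT1, on chromosome 8, was not called with the local median subtracted (adjusted p = 0.113). In the immediate-early and heat shock list (0.396) ATF3, a stress transcription factor, rose by 1.41, while HSPA1A (−1.33) and HSPA1B (−1.41), near-identical copies whose values are uncertain, fell, or 3 and 3 of 12 adjusted over the list alone. The list was called lower without knockout library 1 (adjusted p = 0.0187) or 2 (0.0204). Neuronal markers (0.533) split, with GAP43 (1.69), ENO2 (1.33) and SYP (0.88) higher and NEFM (−1.28) and INA (−1.38), both of the axonal cytoskeleton, lower of 10, or 4 and 2 adjusted over the list alone. SYP was chosen after its value was seen. VIM rose by 1.26 in the mesenchymal list (0.115), 1 of 13, or 3 adjusted over the list alone. That list was called with the local median subtracted (adjusted p = 0.0193) and without knockout library 1 (0.0187) or 2 (0.0364). OAS3 (−1.01) and LGALS3BP (−0.97) fell in the interferon list (0.924), or 2 higher and 2 lower of 19 adjusted over the list alone. LCP1 fell by 0.82 and HLA-DRA rose by 1.05 of 5 blood cell markers (0.533), the same adjusted over the list alone. LGALS3BP (adjusted p = 0.0505) and HLA-DRA (0.0515) were not called with the local median subtracted. Without knockout library 1 or 2 the calls of FDFT1 (0.283 and 0.268), GADD45A (0.251 and 0.271), LCP1 (0.158 and 0.184) and OAS3 (0.0774 and 0.0531) were lost, and without library 1 also those of HMGCS1 (0.0793) and LGALS3BP (0.0605); HLA-DRA was not tested.

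In the mitosis list (camera adjusted p = 0.254) CCNB1 (−0.81) and KIF20A (−0.67), both on chromosome 5, fell, 2 of 19, or 3 adjusted over the list alone. Neither was called with the local chromosome median subtracted (adjusted p = 0.0856 and 0.103), under which the list itself was (0.0432). LDHA, on chromosome 11, fell by 0.62 in the hypoxia list (0.752), or 1 higher and 1 lower of 17 adjusted over the list alone, and was not called with the local median subtracted (0.18). Subtraction likewise ended the calls of RPS27 (0.55, 0.0927 after), 1 of 26 ribosomal protein genes (list 0.931) and 1 adjusted over the list alone, and of HLA-F (0.78, 0.0896 after), 1 of 11 MHC class I genes (list 0.562) and 1 adjusted over the list alone. It also ended those of GATA3 (−0.85, 0.15 after) and PAX2 (0.88, 0.0906 after), 1 lower and 1 higher of 3 kidney markers over all genes and adjusted over the list alone. SDHA, on chromosome 5, fell to 17.9 and 18.3 FPKM from 42 and 34.6, 1 of 14 housekeeping genes (list 0.254) over all genes and adjusted over the list alone. Without knockout library 1 or 2 the calls of CCNB1 (0.139 and 0.16), KIF20A (0.463 and 0.336), LDHA (0.145 and 0.369), RPS27 (0.198 and 0.282), HLA-F (0.261 and 0.311) and GATA3 (0.158 and 0.25) were lost, and without library 1 that of SDHA (0.0567); PAX2 was not tested. Quantile normalization ended those of KIF20A (0.0507), LDHA (0.0561), HLA-F (0.0534) and PAX2 (0.0845). The PAX2 call was also lost with a pseudocount of 0.1 (0.0516), equal medians (0.0523) and a robust prior (0.0524). No member was called of the NF-kB targets (list 0.297; 0 higher and 1 lower of 9 adjusted over the list alone), the TNF receptor signalling list (0.115; 4 lower of 15), the DNA replication genes (0.0584; none of 25) or the imprinted genes (0.533; none of 7). SOD2, of the NF-kB list, had −0.54 (adjusted p = 0.054), and RRM1, of the replication list, −0.48. Both were called lower with all 8 libraries in one fit (limma adjusted p = 0.00647 and 0.0111), and SOD2 also with equal medians (0.0454). The DNA replication list was called lower with equal medians (adjusted p = 0.0395) and with no minimum (0.0332), and the cholesterol list higher with the local median subtracted (0.0325). Of the lists too small to test, germline genes had 1 tested member, TEX15 (−0.65, adjusted p = 0.112, lower adjusted over the list alone). Metallothioneins had 2 and pluripotency genes 2, none of them called over all genes or adjusted over the list alone, TET enzymes 3, with 1 higher and 1 lower adjusted over the list alone, and protocadherin beta genes none. The ribosomal protein list had a median of 0.099 and a mean of 0.043 with camera direction down, and the interferon list a median of 0.136 and a mean of 0.018 with direction down. The TNF receptor signalling list had a median of 0 and a mean of −0.13, and the hypoxia list a median of −0.023 and a mean of 0.024 with direction down.

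A limma contrast over all 8 libraries asked where the effects differed. The IL32 effect was larger with 5Aza-dC than in the libraries labelled knockout, by 2.31 on the log2(FPKM + 1) scale (SE 0.187, limma adjusted p = 0.000431). By the means IL32 was 14.9-fold higher with 5Aza-dC and 5.62-fold higher in the libraries labelled knockout. The B21 values were all under 1 FPKM, where that scale understates a change, so part of the 2.31 comes from the scale. Among the largest differences in that direction were those of CXCL1 (4.12), CCL20 (3.80), PNMA5 (3.58), CXCL8 (3.50) and CTSZ (3.27), the last of which fell by 3.14 in the libraries labelled knockout and had 0.14 with 5Aza-dC. In the other direction were those of STC1 (−3.37), DDIT4 (−3.16), HSPB8 (−3.10), NRN1 (−2.72) and INSIG1 (−2.72). INSIG1 fell by 1.55 with 5Aza-dC and rose by 1.17 in the libraries labelled knockout. Of 16189 genes tested, the 5Aza-dC effect lay above that in the libraries labelled knockout in 2141 and below it in 2583. With equal medians these were 2743 and 1927. The fit pooled its estimate of spread over all 8 libraries. The SD of the log2 difference between replicates was 0.149 for the pair labelled knockout and 0.338 for the B21 controls. The p-values of the contrast therefore do not measure the B21 spread alone, which may be technical. Without B21 knockout library 1 the called genes numbered 2243, without knockout library 2 2478, and without 1 of the untreated or treated libraries 2488 to 2779.

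Genes called in both comparisons moved in opposite directions more often than chance gives. Of 12970 genes tested in both, 243 were called in both. GSTP1, OXCT1, CECR7, STIP1, a co-chaperone, and TRIP13, a checkpoint ATPase, were among 93 genes that rose with 5Aza-dC and fell in the libraries labelled knockout, where independent calls give 56.1 (odds ratio 2.06, Fisher's exact test, adjusted p = 2.28e-07). INSIG1, CPS1, the first enzyme of the urea cycle, ANXA3, GNAO1 and CHRDL1 were among 90 that fell with 5Aza-dC and rose there, where 44.1 are given (2.68, adjusted p = 1.4e-11). CGA, ANKRD1, CDKN1A, ETV4 and VIM were among 29 that rose in both (54.8 given; 0.46, adjusted p = 3.81e-05), and MYOM2, DEAF1, LCP1, GSTA4 and ST6GAL1 among 31 that fell in both (45.1 given; 0.64, adjusted p = 0.0202). The 5Aza-dC call of DEAF1 was lost with no minimum (adjusted p = 0.097), with all 8 libraries in one fit (0.0727) and without treated library 2 (0.0807), untreated control 1 (0.0821) or control 2 (0.0519). That of LCP1 was lost with no minimum (0.0635) and without treated library 1 (0.0669), treated library 2 (0.0548) or untreated control 2 (0.0932), and its other call without knockout library 1 (0.158) or 2 (0.184). With 5Aza-dC the calls of CHRDL1 (0.0662), GNAO1 (0.0657) and OXCT1 (0.0754) were lost with no minimum, the first 2 also without untreated control 1 (0.0518 and 0.0584) and OXCT1 without treated library 1 (0.0533). ST6GAL1 was not called without knockout library 2 (0.0911). Across the genes tested in both, the effects had a Pearson r of −0.199 and a Spearman rho of −0.219. Genes are not independent replicates, and the comparisons share no control library. OXCT1 and TRIP13 lie on chromosome 5, MYOM2 on 8, GSTP1, STIP1 and DEAF1 on 11 and CECR7 on 22, whose medians were below 0. They were still called with the local chromosome median subtracted, STIP1 at −0.70 in place of −1.20, and 76 genes were then called in both. The number called in both was 0 with no minimum, 127 with a minimum of 5 FPKM, 147 without untreated control 1, 59 and 75 without knockout library 1 or 2, and 2145 and 2436 without B21 control 1 or 2.

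**Figure D4:**
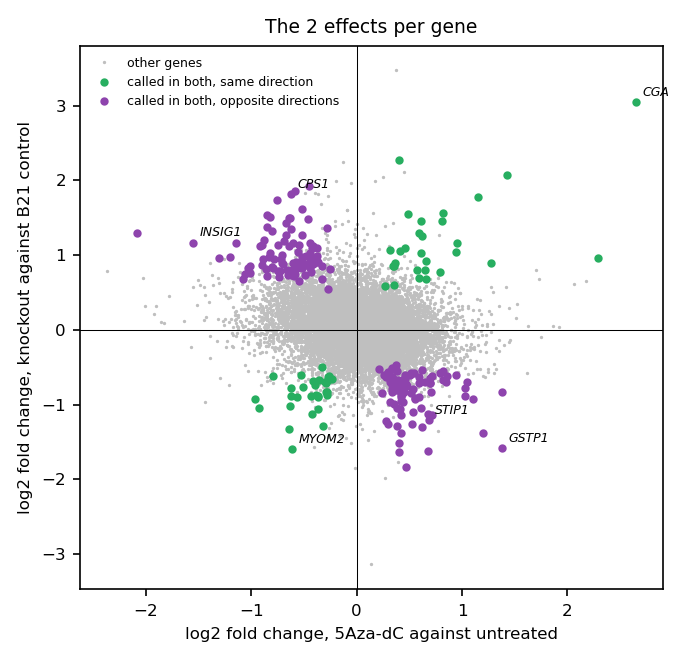
Each point is a gene tested in both comparisons, with its log2 fold change with 5Aza-dC on the x axis and in libraries labelled TET triple knockout on the y axis, both on the log2(FPKM + 1) scale. Of the 243 coloured genes called in both, 183 lie in the quadrants of opposite direction and 60 in those of the same direction.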

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

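Subtracting the local chromosome median and the crossed pairing were chosen after the data were seen, and the other alternatives before. Depth is known only relative to the first library of each experiment, so what it limits was tested through the minimum level alone.

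IL32 rose with 5Aza-dC under every alternative run, with no minimum at an adjusted p = 0.0421. Of 120 named genes called in that comparison, 42 lost their call with no minimum, 6 with quantile normalization, 5 with all 8 libraries in one fit and 2 with the local median subtracted. None of the 120 lost it with a pseudocount of 0.1, equal medians or a robust prior, nor any of the 100 still tested at a minimum of 5 FPKM. Without treated library 1 and 2, 97 of the 120 were tested, CXCL1 and CCL20 not among them, and 12 and 9 lost their call; without untreated control 1 and 2, 119 were tested and 19 and 15 lost it. Of 62 named genes called in the libraries labelled knockout, all 62 lost their call with no minimum, 14 with the local median subtracted, 6 with quantile normalization, 2 each with a pseudocount of 0.1 and equal medians, and 1 with a robust prior. At a minimum of 5 FPKM 47 of the 62 were tested and 1 lost its call, without knockout library 1 and 2, 52 were tested and 19 and 15 lost it, and without either B21 control 56 were tested and none lost it. The 10 named genes of the difference were called under each alternative that tested them. A sign changed in 14 of 274 gene results and 14 of 47 lists without a call in either fit.

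With no minimum 1705 genes changed with 5Aza-dC (36759 tested), 0 in the libraries labelled knockout by limma (4615 at an unadjusted p under 0.05) and 0 in both. This tests more genes near 0, and whether that is the cause was not tested. With a minimum of 5 FPKM 227 genes changed in the libraries labelled knockout and 127 in both, and 6 lists were called with 5Aza-dC and 2 in the libraries labelled knockout, where fewer genes and list members are tested. Asking for 2-fold left 475 and 177 genes by construction. With all 8 libraries in one fit, where the 5Aza-dC pairs add to the estimate of spread, 2614 genes changed in the libraries labelled knockout and 3 lists were called. Quantile normalization left 3 lists there, and the cause was not tested. The share of changed genes that rose in the libraries labelled knockout was 38.2% with equal medians and 40% with quantile normalization against 50.4%, and the share of the difference above was 58.7% with equal medians against 45.3%. With the local median subtracted 171 genes changed there and 76 in both.

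Camera with an estimated correlation called 0 lists in either comparison (2 and 0 at an unadjusted p under 0.05), where camera with the preset called 12 and 6. Fry called 12 lists with 5Aza-dC, 9 of them among those 12 (not the cholesterol, mitosis and ribosomal protein lists). It also called the imprinted (adjusted p = 0.0217), mesenchymal (0.0304) and neuronal (0.0234) lists higher, which camera did not call. In the libraries labelled knockout fry called 0 lists (8 at an unadjusted p under 0.05).

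Replicate numbers as a block gave 1227 genes in the libraries labelled knockout and 499 in both; deviations of same-numbered replicates correlated at 0.03 in the 5Aza-dC experiment and −0.26 in the other, so the numbers do not pair the libraries. A crossed pairing gave 2726 genes. With the replicate numbers as a block the stress list in the libraries labelled knockout lost its call (camera adjusted p = 0.0572). The mesenchymal list was called higher there (camera adjusted p = 0.0446), and DNMT3B was called lower (limma adjusted p = 0.0486).

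Leaving out 1 library leaves a lone library that is assumed to vary like the others. Genes changed with 5Aza-dC then numbered 3608 (without untreated control 1) to 4157, and lists 9 to 11. In the libraries labelled knockout the genes numbered 125 (without knockout library 1), 160 (without knockout library 2), 5328 (without control 1) and 6231 (without control 2), and lists 2 to 7. Without 1 control the spread comes from the knockout pair alone, whose SD of the log2 difference was 0.149 against 0.338 for the controls, so the larger counts follow from the construction. The difference gave 2243 to 6818 genes and the overlap 59 to 2436. The ribosomal protein list in the libraries labelled knockout ran from a median of −0.098 (without control 2) to 0.197 without control 1, where its direction turned up and it was called (adjusted p = 0.0396).

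A robust prior for the lists was not run, since camera takes none, and the germline list had no value at a minimum of 5 FPKM or without 1 treated library. A count test was not run, since whole reads were not recovered.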

Other observations

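The blood cell, 2-fold and chromosome tests below were chosen after the results they bear on were seen: the blood cell markers, the share kept among genes changed at least 2-fold and the size of their changes with their bounds set afterwards, and the local median tests after the chromosome medians. The X chromosome and chromosome 11 were also picked after their values were seen.

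Genes of the X chromosome were frequent among those that rose at least 2-fold in both comparisons. With 5Aza-dC, where 481 X genes were tested, they were 23 of 232, PNMA5, ACRC and SSX1 among them (odds ratio 3.8, Fisher's exact test, adjusted p = 8.26e-06 over chromosomes). In the libraries labelled TET triple knockout they were 15 of 112, led by SYTL5, which did not pass with 5Aza-dC (odds ratio 4.57, Fisher's exact test, adjusted p = 0.000116). There the 436 tested X genes had a median log2 fold change of 0.158, against 0.067 over all tested genes. The X count was not repeated with the local median subtracted, so a shift of the whole chromosome may contribute. On chromosome 11, 10 genes fell at least 2-fold in the libraries labelled knockout (odds ratio 3.31, Fisher's exact test, adjusted p = 0.046). These Fisher tests took only genes placed on an autosome or the X chromosome, so not all of the 232 and 112 entered them.

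Of 23 NF-kB target genes 16 rose with 5Aza-dC, CXCL1 and IL32 among them, while 6 did not pass and IER3 fell, and the list was not called with an estimated correlation (camera adjusted p = 0.403). Its median log2 fold change of 0.65 (0.40 and 0.43 without treated library 1 and 2) lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 0.34. The matching used the mean of all 4 libraries, treated ones included, and 7 of the 23 were under 1 FPKM in both untreated libraries. Genes low in the controls were thus not compared with genes equally low there. These lists therefore cannot decide whether the wider spread of genes with low values contributed. RNA of blood cells in the treated libraries is argued against by the list of 13 blood cell markers (5 of them at 1 FPKM or more in a control, where a small share would be hidden): CD74 alone, 1 of 13, was higher by 1 FPKM or more in both treated libraries, at 5.8 and 5.88 FPKM against 0.351 and 0.66, while HLA-DRA stood at 0.356 and 0.225, PTPRC at 0.0674 and 0.237, CD53 at 0.0346 and 0.15, LAPTM5 at 0.538 and 0.355 and TYROBP at 0, far below CD74. TNF was at 1.64 and 1.41 FPKM in the treated libraries, the lowest being 1.41, against 0.187 and 0.0638, so TNF made by the treated cells may contribute, as may loss of methylation at the targets themselves, which was not tested. TNF is itself an NF-kB target, so its level cannot say which came first.

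Genes changed in the libraries labelled TET triple knockout lay near genes that moved with them: 70.8% of the 10 nearest tested neighbours went the same way, against 50.23% to 55.9% in 1000 shuffles of positions. The differences by chromosome between the B21 control libraries may contribute to this, which was not tested. Copy number differences between the cells compared may likewise account for part of the calls, and neither DNA nor copy number was analysed here. As the whole cause they cannot be told apart from an effect of the knockout: with the local median subtracted 30.1% of the 528 calls were kept, 60.5% of the 177 genes changed at least 2-fold kept their call at 2-fold or more, and smaller deletions or gains would escape the subtraction. The local medians of the tested genes ran from −0.511 to 0.493, short of the 2-fold change that defines these 177. That argues against shifts over about 100 genes as their whole cause. Subtraction took their median absolute log2 fold change from 1.25 (quartiles 1.09 and 1.46) to 1.17 (0.97 and 1.44). The selection and the small local medians kept that median high in advance, so it is no further evidence. Of the 55 that lost their call 44 stayed within the former limit of an unadjusted limma p of 0.00197, which fell to 0.00064 as fewer genes passed. A difference between clones unrelated to TET also stays open, since the labels do not say how many clones the libraries came from.

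The effects of 5Aza-dC and in the libraries labelled TET triple knockout ran in opposite directions, as in GSTP1 and INSIG1. The comparisons share no library, so independent noise of genes with low values would pull r towards 0, and an r among other genes is no test of it. The pattern was not limited to genes with low values: the 5698 genes at 10 FPKM or more in all 8 libraries had a Pearson r of −0.209. Chromosome-scale shifts are argued against by an r of −0.201 with the local median subtracted in both comparisons. A culture state that also varies between replicates cannot be told apart from the effects: the 5Aza-dC effect had an r of 0.082 with the difference of the B21 control libraries and of −0.102 with that of the libraries labelled knockout, and the bound set for an exclusion assumed separate cultures, which nothing states of these libraries. Over 15 alternatives r ran from −0.215 to −0.136 and, where any gene was called in both, the share with opposite signs from 63.3% (without B21 control 1) to 78.9% (without untreated control 2). Methylation was not analysed here, and no biological explanation was tested.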
